A study of Rattus norvegicus with 2 samples.

How the data were processed

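Total RNA from the hearts of Dahl salt-sensitive rats on a high-salt or a low-salt diet was converted to biotin-labelled cRNA by in vitro transcription and fragmented, per the labels' protocols, and read on 1-colour arrays. The probe set and control names are those of Affymetrix rat arrays. The authors deposited 1 intensity value per probe set and array, on a linear scale. The software that made these intensities, its settings and any detection calls are not given in the sources used here. The deposited intensities include values below 0, as a difference between matched and mismatched probes gives, and the 2% trimmed means of the arrays differed by 0.0030%, so the arrays had been scaled to a common level before deposit. All value columns were matched to a sample. Groups were taken from the source names, with 1 array in each.

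The gene lists, the main settings and the alternatives other than those named as later choices were fixed before the data were examined. The table was to count as already normalized if the trimmed means differed by less than 10%, so the values were used as deposited. A floor was set at the 40th percentile of all values of both arrays without controls, which was 10.9, and lower values were raised to it before the log2 ratio of high salt over low salt was taken. Where 1 of the 2 values was under the floor the ratio is a bound, and where both were the gene was left out. Probe sets were named from the platform annotation of 2016: of 8740 non-control probe sets, 7006 had 1 gene symbol, 308 had several and 1426 had none, and genes were named from those with 1 symbol alone (4736 symbols). Where a gene had several probe sets, the one with the highest mean log2 value was used. A gene counted as higher or lower at 2-fold. Named genes were the 10 highest and 10 lowest with both values above the floor, the 5 largest bounds in each direction, Alox15, Ccl2, the eicosanoid genes past 2-fold, up to 4 members of each of 23 gene lists with the largest ratios, and members of the marker and reference lists where these are discussed. Other members of these lists, and genes outside this rule such as Tsc22d1, Hba-a3, Tef and clock genes, were chosen after their values were seen. A RefSeq gene table of the rat was not used, and no genome coordinates are given, because no build was named.

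The floor of 10.9 lay within the noise of the arrays, where values below 0 were often larger in size. A second, noise floor was therefore chosen after seeing the data: the 95th percentile of the size of all values below 0, which was 126.4. On the high-salt array 20.0% of the probe sets reached it, and on the low-salt array 20.3%. It stands in for a detection call and is not one. A value described as dim or under the noise floor has no reliable order, and ratios "against the noise floor" raise both values to 126.4 first.

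With 1 array per group no test across genes, standard error or p-value was computed. The error of a ratio within this pair of arrays was described by the pooled SD of the log2 ratio among probe sets of the same gene. A gene list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn from 10 brightness bins, where at least 4 members were measured; this describes the 2 arrays and not the diets in general. The ratio, count and list steps were tested on simulated arrays made from the low-salt values, with changes given to bright genes alone, so the test says nothing of dim ones. At log2 changes of 2 and -2, 100% and 98% of 50 genes each passed the 2-fold rule, and at 1.5 and -1.5, 98% and 94% did. The simulated log2 ratios varied with an SD of 0.22, plus additive noise well under the noise floor, and held no variation between animals. Recovery therefore shows that the steps compute as meant, and not how reliable the 2-fold rule is on real arrays. A simulated list of 24 genes shifted by -0.75 gave a median of -0.74 at percentile 0. Alternatives were 2% trimmed mean, quantile, loess (span 0.4) and median scaling, other floors, log2(value + 1) without a floor, other rules for several probe sets, 1.5-fold and 3-fold thresholds, and other memberships of the lists. Adding the noise floor and leaving out probe sets that may share sequence were chosen after seeing the data, as was the median of the natriuretic peptide list without Nppa. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9.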

Results

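Heart tissue of male Dahl salt-sensitive rats, an inbred strain that becomes hypertensive when fed salt, was profiled on 1-colour oligonucleotide arrays at an age of 17 weeks. One array held RNA of the high-salt diet, for which the labels give chronic heart failure, and 1 array held RNA of the low-salt diet. The labels do not state whether each RNA came from 1 animal or a pool, nor which chamber of the heart was taken. Each array reported 8799 probe sets, of which 59 were controls. The 2% trimmed mean intensity was 100.2 on both arrays, and the values ranged from -763.8 to 8962.4 on the high-salt array and from -947.9 to 9328.7 on the low-salt array. Intensities below 0 made up 27.3% of the probe sets on each array. With 1 array per diet there was no spread between replicates, so every difference below compares these 2 arrays and carries no p-value; the number of arrays limits the precision. As a partial measure of error, the log2 ratio differed between probe sets of the same gene with an SD of 0.47 (736 genes), or 0.22 among the 231 genes with at least 2 probe sets above a noise floor of 126.4 on both arrays. That error holds no variation between animals.

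The high-salt and low-salt hearts were compared to find the genes whose RNA level differed in the failing heart. Alox15, which encodes the lipoxygenase named in the title of the study, had the highest ratio of all 3451 genes measured. Its brighter probe set, S69383_at, read 2433.7 in the high-salt heart and 25.9 in the low-salt heart, a 94.0-fold difference. The other, L06040_s_at, read 2062.6 and -112.9. Because both low-salt readings lay under the noise floor, the ratios are better stated as bounds: at least 19.2-fold and at least 16.3-fold higher, respectively, against that floor. Reg3b, a secreted lectin of the regenerating protein family, followed with 1306.8 against 32.0, at least 10.3-fold higher against the noise floor. Most red blood cell probe sets were higher on the same array, with Hbb 2.40-fold and Alas2 at least 5.52-fold higher. At 2-fold or more, 252 genes were higher and 251 were lower in the high-salt heart, and 2948 were neither. With both arrays held to the noise floor, a level chosen after the data were seen, 1216 genes remained, of which 43 were higher and 23 lower. There, 28 of the higher and 14 of the lower genes reached the noise floor on both arrays. Of 101 genes past 2-fold that had several probe sets, 32 had a probe set that showed no difference or the opposite direction.

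**Figure D1:**
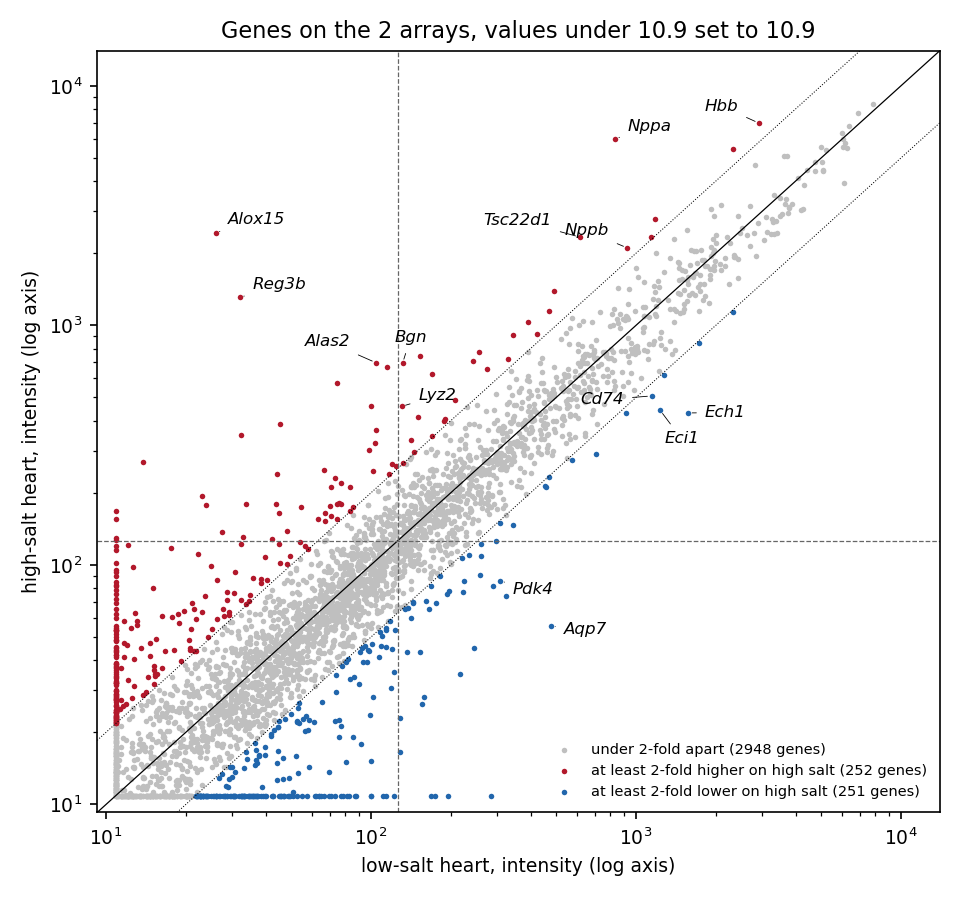
Intensity of each gene in the high-salt heart (vertical, log axis) against the low-salt heart (horizontal, log axis), 1 point per gene and 1 array per diet. The solid line marks equal values, dotted lines 2-fold, and dashed lines the noise floor of 126.4; Alox15 (2433.7 against 25.9) and Reg3b (1306.8 against 32.0) lie apart from the other genes.

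Among genes read above the lower floor of 10.9 on both arrays, the 10 highest ratios were those of Alox15, Reg3b and the 8 described next. G0s2, an inhibitor of triglyceride breakdown, read 268.3 against 13.8, and Plscr3 350.2 against 32.4. Csrp2, a LIM domain protein, read 387.9 against 45.2. Akip1 read 574.1 against 74.3, although the lowest of its 3 probe sets had a log2 ratio of -0.19. The interferon-induced gene Rsad2 read 194.7 against 23.1 and Spp1, which encodes osteopontin, read 177.6 against 23.9. Gpr161 and Serpina1fl1 completed this set and stayed under the noise floor on both arrays. Read against the noise floor, the bounds were 4.54-fold for Akip1, 3.07-fold for Csrp2, 2.77-fold for Plscr3, 2.12-fold for G0s2, 1.54-fold for Rsad2 and 1.40-fold for Spp1. Where the low-salt value was under the lower floor, the 5 largest bounds were those of Postn, Pcp4, Tnfrsf1a, Hs6st1 and Gna15. Their high-salt intensities were between 120.4 and 167.3, so none exceeded the noise floor by more than 1.32-fold.

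The 10 lowest ratios were led by Aqp7, a glycerol channel, at 55.6 in the high-salt and 478.1 in the low-salt heart, at least 3.78-fold lower against the noise floor. Fkbp4, a co-chaperone, read 45.2 against 245.7, with all 3 of its probe sets lower, and RT1-DOa, of the major histocompatibility complex, read 35.0 against 216.0; the bounds were 1.94-fold and 1.71-fold. Galnt5, Mamdc4, Gfy and Ces1d were also in this set, with low-salt intensities of 129.2, 156.1, 158.2 and 128.6 that were close to the noise floor, and Rabep2, Il3 and Apoc1 never reached it. Of the genes under the lower floor in the high-salt heart, Dbp, a transcription factor driven by the circadian clock, had the largest bound. It read -39.2 against 284.5, at least 2.25-fold lower against the noise floor. Araf read 10.2 against 194.8, Dhrs7c -2.7 against 174.3, Gpam, an enzyme of triglyceride synthesis, 9.5 against 168.1, and Supt5h -12.5 against 122.1. All 3 Supt5h probe sets were under the noise floor, and they did not share a direction.

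Natriuretic peptide transcripts were abundant and higher in the high-salt heart. Nppa, which encodes atrial natriuretic peptide, read 5997.7 against 833.4 in its brightest probe set, a 7.20-fold difference, and its 4 probe sets ranged from 7.20-fold to 22.2-fold. Nppb, which encodes brain natriuretic peptide, was 2.27-fold higher at 2104.3 against 927.2. Of 13 measured genes in the list of natriuretic peptides and the fetal gene programme, 4 were at least 2-fold higher, none at least 2-fold lower, and 9 neither. The other members past 2-fold, Npr3 (58.4 against 13.1) and Myl4 (38.4 against -9.6), lay under the noise floor. Skeletal alpha-actin, Acta1, read 3181.4 against 2096.2, and Ankrd1 5086.3 against 3604.8. The slow myosin heavy chain Myh7 read 6372.0 against 5980.7 in its brighter probe set and was 2.08-fold higher in the other; both are of types that can share sequence with related genes. The median log2 ratio of the list was 0.50 (quartiles 0.09 and 1.18), at percentile 99.9 of 10000 random lists matched on brightness; it was 0.27 with the lower floor moved to the 60th percentile. Of the 3 measured atrial markers, Nppa was the one above the noise floor; Myl4 and Myl7 (96.0 against 95.5) lay under it in all their probe sets and give no direction.

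Of 12 measured sarcomere genes, 11 were within 2-fold in their brightest probe set and Csrp3, a muscle LIM protein, was higher at 2331.6 against 1135.3. Des, which encodes desmin, read 2870.1 against 1961.6, Ldb3 720.6 against 1112.1 and Tcap 1794.8 against 2068.3. The cardiac myosin heavy chain Myh6 read 4416.3 against 4739.8 in its brightest probe set, but its 3 probe sets, all of a type that can share sequence with related genes, had log2 ratios from -0.94 to -0.10. The list median was -0.08 and its mean 0.04, and the median stood at percentile 42.7 of the random lists.

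Extracellular matrix and remodelling genes were higher as a group. Of 32 measured genes, 9 were at least 2-fold higher, none at least 2-fold lower, and 23 neither, with a median log2 ratio of 0.40 (quartiles -0.09 and 1.34) at percentile 100 of the random lists. The median was 0.26 against the noise floor and 0.20 over members above the lower floor on both arrays, at percentiles 99.8 and 99.7. The housekeeping and ribosomal reference list had medians of 0.15 at the lower floor and 0.14 against the noise floor. These lay at percentiles 99.4 and 99.1, so the percentiles alone do not set the matrix list apart. Postn (167.3 against 5.0), which encodes periostin, Eln (81.4 against -1.7), which encodes elastin, Spp1 (177.6 against 23.9) and Tgfb2 (75.4 against 8.9) had the largest ratios. Among abundant collagens, Col1a1 read 1169.7 against 823.3 and Col1a2 292.8 against 193.8, whereas Col3a1 read 545.4 against 599.5. Against the noise floor, 20 members were measured and Bgn, which encodes the proteoglycan biglycan, was the only one past 2-fold, at 695.2 against 131.6 (5.28-fold). A second, dimmer Bgn probe set went the other way, with a log2 ratio of -3.46. For Fn1, which encodes fibronectin, the probe sets likewise ran from a log2 ratio of -1.61 to 1.65. Of 9 fibroblast markers, only S100a4 passed 2-fold, at 461.8 against 99.8, while Vim read 975.5 against 564.8, Ddr2 -4.9 against 21.0 and Thy1 23.4 against 15.6. The fibroblast list had a median of -0.08 and a mean of 0.24, with the median at percentile 44.3. Over 12 alternatives that median ran from -0.35 to 0.51, with percentiles from 10.5 to 99.85, so the list has no settled direction. It lay outside the central 95% of random lists in 1 of them.

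Genes of fatty acid oxidation were lower in the high-salt heart. Of 29 measured, 27 had a ratio below 1, 9 were at least 2-fold lower and none was at least 2-fold higher, and 20 were neither. The median log2 ratio was -0.67 (quartiles -1.06 and -0.32), a 1.60-fold lower level, and lay at percentile 0 of the 10000 random lists. Ech1, a peroxisomal and mitochondrial dienoyl-CoA isomerase, was 3.65-fold lower at 430.9 against 1571.3. Eci1, an enoyl-CoA isomerase, was 2.78-fold lower at 442.7 against 1232.2, and all 3 of its probe sets were lower. Pdk4, a kinase that inhibits pyruvate dehydrogenase, read 85.6 against 307.3, and the acyl-CoA thioesterase Acot2 110.3 against 234.8. Acadvl, Cpt2, Acaa2, Decr1 and Slc25a20, which act in mitochondrial fatty acid import and the oxidation cycle, were between 2.05-fold and 2.13-fold lower. The high-salt readings of Pdk4, Acot2 and Slc25a20 lay under the noise floor. Against that floor these genes were at least 2.43-fold, 1.86-fold and 2.05-fold lower, respectively. Of the 24 members that reached it on an array, 8 were at least 2-fold lower against it, with a median log2 ratio of -0.75 at percentile 0. Fabp3, the heart fatty acid binding protein, read 3932.1 against 6103.4. The uncoupling protein gene Ucp2, at 1825.2 against 1446.8, and the dim gene Hadh were the members with a ratio above 1.

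**Figure D2:**
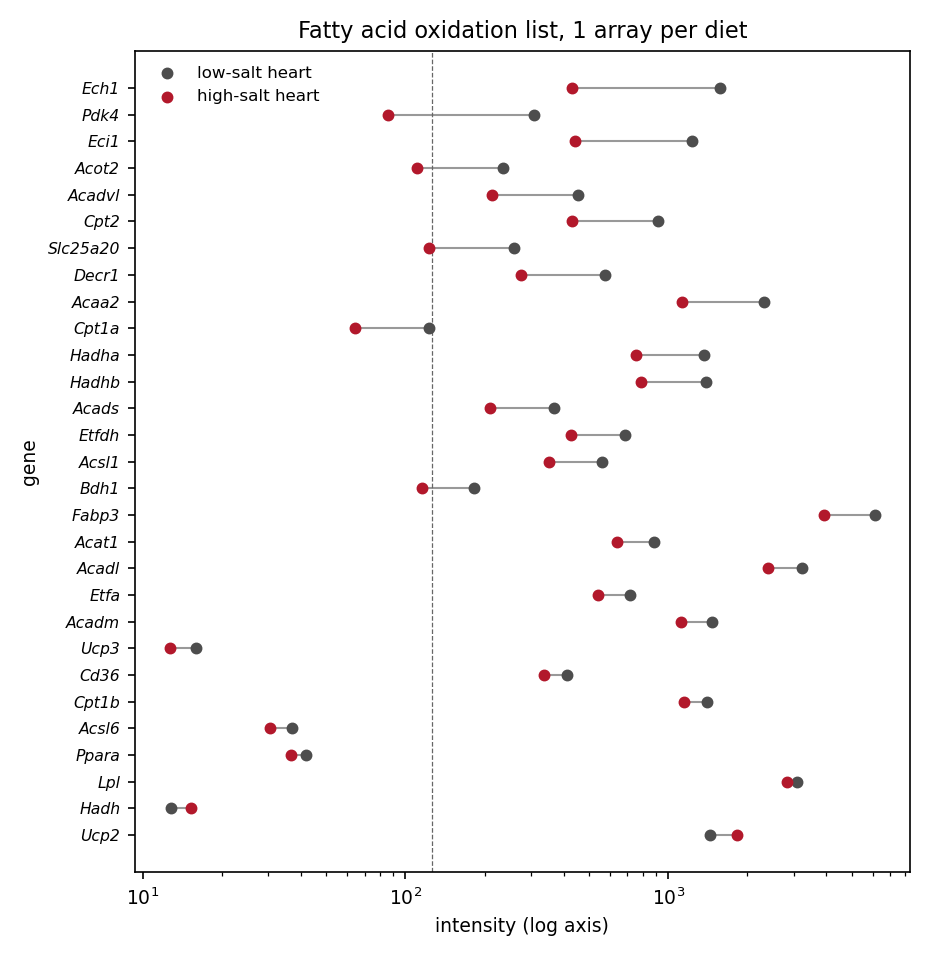
Intensity (log axis) of each measured gene of the fatty acid oxidation list in the low-salt and high-salt hearts, 1 array per diet, ordered by ratio. The dashed line is the noise floor of 126.4; 27 of the 29 genes read lower in the high-salt heart, from Ech1 at 3.65-fold lower.

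Genes of the citrate cycle and respiratory chain differed less. None of the 36 measured genes of this list reached 2-fold, but 30 had a ratio below 1, and the median log2 ratio of -0.28 (quartiles -0.34 and -0.10) lay at percentile 0.09. Got1 read 600.3 against 1043.8, Suclg1 859.8 against 1344.9, Ndufs1 101.1 against 153.1 and Ndufa5 1494.3 against 2248.3. The complex I genes Ndufb10 and Ndufs7, which are not in the list and were chosen after their values were seen, were 2.06-fold lower. Glucose uptake and glycolysis genes went both ways, with 1 of 22 at least 2-fold higher, 3 at least 2-fold lower and a median of -0.11 (percentile 31.5). The glucose transporter Slc2a1 read 247.1 against 101.7. The muscle isoforms Pgam2 (77.4 against 221.7) and Eno3 (125.6 against 296.4) were lower, and the third, Pfkfb2 (4.0 against 22.8), was under the noise floor. Against that floor Slc2a1 was at least 1.95-fold higher and Pgam2 at least 1.75-fold lower, which left Eno3, at least 2.34-fold lower, as the one past 2-fold.

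Apart from Alox15, no eicosanoid gene passed 2-fold against the noise floor. In this list of 19 measured genes, 4 were at least 2-fold higher and 2 lower, with a median of 0.18 at percentile 96.7, or 0.36 at percentile 93.3 over the 4 genes that reached the noise floor. Alox5 read 43.5 against -0.5, Ptgds, a prostaglandin D synthase, 108.1 against 39.9, Ptgfr 111.4 against 22.3 and Cyp4a1 -1.2 against 46.8, all under the noise floor. Ephx1, an epoxide hydrolase, read 75.3 against 194.1, at least 1.54-fold lower against that floor. Of 24 measured chemokine, cytokine and adhesion genes, 4 reached the noise floor on an array, among them Nfkbia, an inhibitor of NF-kappa-B, at 174.0 against 283.5. Ccl2, the monocyte chemoattractant, read 101.6 against 45.5, a 2.23-fold difference under the noise floor, and its other probe set gave 1.88-fold. In this list, 5 were at least 2-fold higher and 2 lower, with a median of 0.13 at percentile 95.4. None passed 2-fold against the noise floor, and the median was -0.019 with each gene at the median of its probe sets. Those past 2-fold at the lower floor included Tnfrsf1a (129.8 against -6.1), Cx3cl1 (159.3 against 70.6) and Lbp (-58.4 against 57.3).

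Leukocyte markers went both ways. Of 16 measured, 3 were at least 2-fold higher and 2 lower, with a median of 0.04 at percentile 79.9, which was -0.04 over the 8 that reached the noise floor. Lyz2, which encodes lysozyme of macrophages and neutrophils, was 3.52-fold higher at 458.6 against 130.4. Cd74, the invariant chain of antigen-presenting cells, was 2.26-fold lower at 507.3 against 1144.4, and all 4 of its probe sets were lower. S100a8 (48.4 against -6.1), S100a9 (62.6 against -6.1) and Cd37 (22.4 against 73.3) stayed under the noise floor.

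Calcium handling genes included no member past 2-fold among 19 measured, with a median of -0.25 at percentile 8.36. Over 12 alternatives that median ran from -0.49 to -0.17, and it lay outside the central 95% of random lists in 1 of them. The sarcoplasmic calcium pump Atp2a2 read 4426.7 against 5065.0, with log2 ratios from -1.15 to -0.19 over its 4 probe sets, and S100a1 154.6 against 254.4; Ppp1r1a, Atp2b1 and Camk2g were under the noise floor. Of 7 measured ion channel and sodium pump genes, Kcne1 passed 2-fold (137.1 against 27.5), barely above the noise floor. Kcnj11 read 179.6 against 290.8, Kcnh2 56.2 against 92.8 and the sodium pump subunit Atp1b1 785.9 against 1070.1. The median was -0.44, the mean 0.01 and the percentile 3.18. In the renin-angiotensin, endothelin and adrenergic list, with a median of 0.12 at percentile 91.1 over 16 genes, Hsd11b1, which regenerates active glucocorticoid, was 2.76-fold higher at 413.9 against 149.9. The alpha-1B adrenergic receptor gene Adra1b read 106.8 against 220.6, at least 1.74-fold lower against the noise floor, Agt -51.9 against 36.0 and Adm 53.7 against 28.6. Immediate early and heat shock genes had a median of 0.22 at percentile 98.9 but a mean of -0.03 over 19 genes. Ier3 read 265.3 against 131.6, while Hspa1a (19.2 against 75.5), Junb (48.8 against 20.5) and Dnajb1 (29.8 against 55.6) were dim. Probe sets shared by Hsp90aa1 and Hsp90aa1-ps17 were left out because they have several symbols. They read higher in the high-salt heart, at 1395.6 against 639.5 and 334.5 against 149.1. Antioxidant, glutathione and metallothionein genes had a median of -0.01 and a mean of 0.07 over 23 genes (percentile 67.8). Their only measured metallothionein was the dim Mt3 (55.3 against 78.4). A probe set shared by Mt1m and Mt2A, left out because it has several symbols, read 481.3 against 233.4. Gstm1 read 277.4 against 140.3, and the dim genes Gclm, Hmox2 and Gclc had log2 ratios of 1.60, -0.83 and -0.76.

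Markers of other cells and tissues were read in the same way. All 3 measured red blood cell markers were at least 2-fold higher in the high-salt heart in their brightest probe set, but not in every probe set. Alas2, the first enzyme of haem synthesis in red cell precursors, read 698.0 against 104.5, at least 5.52-fold higher against the noise floor. The globin gene Hbb read 6982.3 against 2910.5 and the anion exchanger Slc4a1 264.6 against 119.8, although another of the 3 Slc4a1 probe sets read 168.3 against 174.8. Probe sets shared by several globin genes were 1.92-fold higher for Hba-a1 and Hba-a2 and 1.22-fold higher (3526.6 against 2879.3) for the beta-globin genes. Skeletal muscle markers had a median of -0.35 over 9 genes (percentile 9.77), with Chrna1, Myh4 and Atp2a1 dim. Smooth muscle markers had a median of 0.48 over 6 genes (percentile 92.2), with Tpm2, Myh11, Actg2 and Tagln all under the noise floor. Endothelial markers had a median of 0.08 over 6 genes (percentile 73.3), of which 2 reached the noise floor on an array. Flt1 read 121.3 against 127.9, barely reaching that floor. Pecam1 (117.5 against 107.4), Kdr (43.6 against 21.5) and Vwf (14.3 against 5.7) lay under it. Nos3 lay under it as well, with log2 ratios from -0.03 to 2.83 over 5 probe sets. Adipocyte markers had a median of 0.09 over 4 genes (percentile 74.6), with Fabp4 at 613.4 against 785.0 and Lep at 531.1 against 453.6. Lipe (59.5 against 44.5) and Ucp1 (25.6 against 26.5) were under the noise floor. Liver and plasma markers had a median of -0.20 and a mean of -0.01 over 6 genes (percentile 29.1). Ttr read 282.3 against 141.3 and Apoc3 177.0 against 144.5, while Apoa1 (42.5 against 51.9) and Fgb (7.3 against 17.3) were under the noise floor.

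The reference list of housekeeping and ribosomal genes had a median log2 ratio of 0.15 over 37 genes, at percentile 99.4. A list taken as a reference thus also lay high among the random lists, so such a percentile does not by itself mark a difference with diet. The same limit holds for the high percentiles of the natriuretic peptide, extracellular matrix and immediate early lists. Rpl3 was 2.66-fold higher at 912.9 against 342.9. Eef1a1 read 1041.2 against 632.8, and Rps24 and Rpl17 were dim. As a measure of RNA integrity, the ratio of the 3-prime to the 5-prime control probe set was 1.30 and 1.22 for Gapdh and 1.16 and 1.10 for beta-actin, in the high-salt and low-salt hearts. For hexokinase, whose 3-prime and 5-prime readings were under the noise floor, it was 2.12 and 2.35. The spiked bacterial transcript CreX read 1.27-fold and 1.24-fold higher on the low-salt array at its 3-prime and 5-prime probe sets, and BioDn 1.14-fold higher there at both, whereas BioC read 1.06-fold and 1.11-fold higher on the high-salt array.

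**Figure D3:**
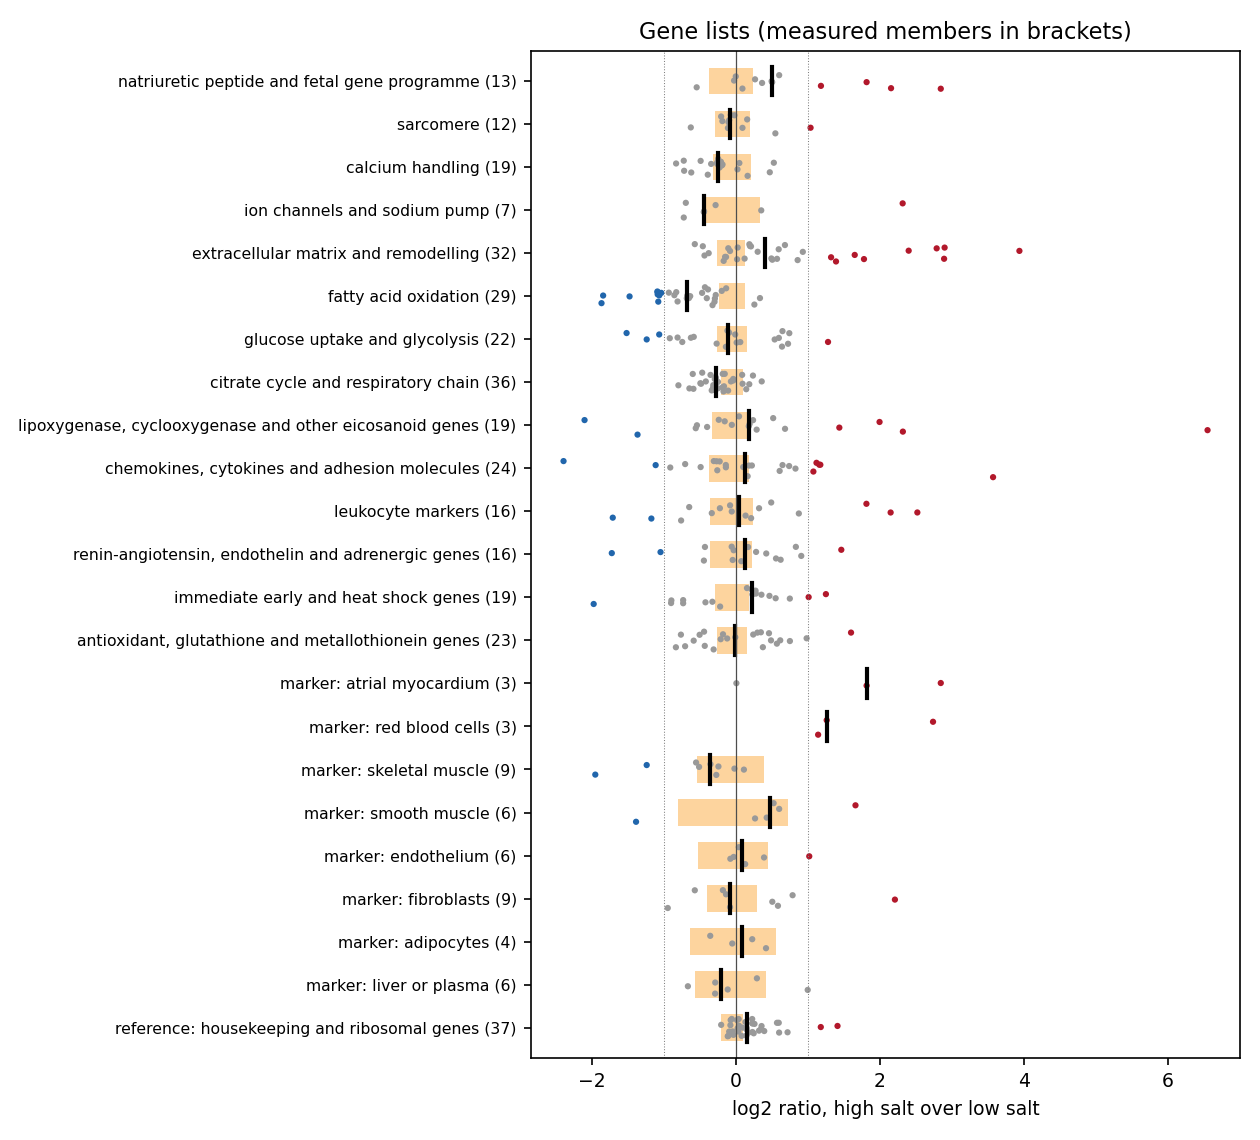
Log2 ratio of high salt over low salt (horizontal) for each measured member of the 23 gene lists (1 point per gene), with the list median as a black bar and the central 95% of medians of random brightness-matched lists as a shaded band where at least 4 members were measured. The fatty acid oxidation median (-0.67) lies left of its band and the extracellular matrix median (0.40) right of its band; dotted lines mark 2-fold.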

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

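The noise floor, the omission of probe sets that may share sequence and the natriuretic peptide list without Nppa were chosen after seeing the data. Signal over background limited these arrays. The number of genes at least 2-fold higher in the high-salt heart (252) and of genes at least 2-fold lower in the high-salt heart (251) became 104 and 87 with the floor at the 60th percentile, 463 and 476 without a floor and 43 and 23 with the noise floor, where the share of higher genes among those past 2-fold went from 50.1% to 65.2%. They were 483 and 599 at 1.5-fold, 114 and 99 at 3-fold, and 414 and 435 when probe sets were counted in place of genes. Under the scaling alternatives that share lay between 50.2% and 57.6%, and the median ratio of all genes moved from -0.08 to -0.01 at most; setting the trimmed means equal changed almost nothing, because they were equal already. The Alox15 log2 ratio of 6.55 was 5.88 with the floor at the 60th percentile, 7.06 as the median of its probe sets, 7.56 with the larger one and 4.27 with the noise floor; among genes it ranked first under every scaling, floor and probe set rule except without a floor, where it ranked 6. The fatty acid oxidation median of -0.67 became -0.80 with the median and -0.83 with the largest ratio over probe sets. The extracellular matrix median of 0.40 became 0.53 with the largest ratio, 0.26 with the noise floor and 0.20 with members above the floor on both arrays. The natriuretic peptide list gave 0.27 with the floor at the 60th percentile. The eicosanoid list gave 0.36 with the noise floor and 0.07 at its lowest, and lay outside the central 95% of random lists in 1 of 12 alternatives. The chemokine list gave 0 without a floor and -0.019 with the median and with the largest ratio over probe sets. Apart from the floors and thresholds, which keep fewer or more genes by construction, the cause was not tested. The medians of the fatty acid oxidation, extracellular matrix, respiratory chain and reference lists stayed outside the central 95% of random lists in all 12 alternatives, and that of the natriuretic peptide list in all 13, Nppa left out included; the immediate early list did so in 9 of 12. The reference list is among those that stayed outside, so staying outside does not by itself mark a difference with diet. The medians of the chemokine, leukocyte, antioxidant, ion channel, renin-angiotensin, fibroblast, adipocyte and liver lists turned sign or reached 0 under at least 1 alternative. The spread between probe sets of 0.47 became 0.22 with the noise floor. Of the named genes past 2-fold, Supt5h turned from lower to higher (1.22) without a floor, when another of its probe sets became the brightest. Changes of direction were not counted for named genes under 2-fold. Over all named genes, 964 other values stayed within 1 SD between probe sets and 105 did not. The floor at the 20th percentile was not run, since it lies below 0. No paired analysis was possible because each diet had 1 array, and no replicate could be left out.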

Other observations

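Beyond the lists of the report, several abundant genes differed in the high-salt heart. These genes, and the tests of Alox15 against a single probe set, red blood cells and young red cells, were chosen after the values were seen. The leukocyte and clock tests below also use the noise floor, so their cutoffs were not fixed before the data were examined. Tsc22d1, a transcriptional regulator induced by transforming growth factor beta, was 3.82-fold higher at 2336.8 against 612.2. Pmepa1, a feedback inhibitor of that pathway, was 2.91-fold higher at 707.0 against 243.2, and Fstl1, a secreted follistatin-like protein, 3.68-fold higher at 627.6 against 170.6. Anxa5, which encodes annexin A5, was 2.86-fold higher at 1395.2 against 488.4, Prnp 3.03-fold at 772.2 against 255.0, and Ivns1abp at least 5.31-fold at 671.4 against 114.6. On the lower side, Pxmp2, a peroxisomal membrane channel, was 2.35-fold lower at 146.3 against 343.4, the retinoid receptor gene Rxrg 2.17-fold lower at 210.9 against 458.0, and the complex I genes Ndufb10 and Ndufs7 both 2.06-fold lower. Of 366 probe sets without a single gene symbol that reached the noise floor on an array, 12 were at least 2-fold higher and 2 lower.

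Alox15 was far higher in the high-salt heart. An error at 1 probe set is argued against, since both probe sets were at least 16.3-fold higher against the noise floor. A larger amount of red blood cells of unchanged content would raise all their transcripts about as much as an Alox15 transcript they carried. Yet the highest of 6 red cell probe sets above the noise floor on both arrays, that of Hba-a3, was 4.88-fold higher. That is under the cutoff chosen for this test, 9.62-fold, which was itself set below the Alox15 bound of 19.2-fold. The rule left out Alas2 and the Slc4a1 probe set at 264.6 against 119.8, whose low-salt readings lay under the noise floor. The globin probe sets with low-salt readings from 2317.7 to 3600.9 could not have passed the 9.62-fold cutoff. No reading on the high-salt array exceeded 8962.4. The argument therefore rests on Hba-a3, at 746.9 against 152.9, and the Slc4a1 probe set at 168.3 against 174.8. More leukocytes of every kind are argued against in the same way, over 8 markers that reached the noise floor on an array. The upper quartile of the ratios of their values as read was 1.33-fold (a log2 ratio of 0.28 with values raised to the noise floor), and the highest, Lyz2, was 3.52-fold. C1qb (178.1 against 97.1) and Cd14 (149.1 against 128.7) also read higher, and Cd48 (122.0 against 126.9) slightly lower. Cd74, RT1-Da, RT1-Ba and RT1-Db1 all serve antigen presentation and read lower, so the quartile partly reflects that function. More young red cells may still account for part of the Alox15 signal, because Alas2 was at least 5.52-fold higher with a low-salt value under the noise floor, so its ratio has no upper limit; a single leukocyte type, a change within heart cells with the disease, and differences between individual animals remain open and untested.

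The lower fatty acid oxidation genes could reflect a smaller share of heart muscle cells in the tissue. Sarcomere genes were not as low: 6 of them within the brightness span of the fatty acid list had a median log2 ratio of -0.09. This was higher than that of the fatty acid list by 0.59, at percentile 99.5 of differences between random lists. However, the dimmest of the 6, Ldb3, read 720.6 against 1112.1, while the median readings of the fatty acid list were 426.5 and 684.0. The 6 also held Csrp3 and Des, which read higher in the high-salt heart. Because the 6 were brighter than much of the fatty acid list, the comparison leaves a smaller share of muscle cells open. A bias that depends on brightness is argued against, since the list median lay at percentile 0 of random lists matched on brightness. After loess it was -0.63, again at percentile 0. That adds little, because loess removes a trend with the same brightness on which the lists were matched. A change of expression in muscle cells with the diet or heart failure stays open as a hypothesis, as do differences in feeding before collection and between individual animals, neither of which was tested.

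Dbp and Tef, related transcription factors whose RNA cycles with the circadian clock, were both lower in the high-salt heart, Tef at 108.7 against 259.4. Hearts collected at different clock times are a candidate explanation. Only 1 other clock gene, Nr1d1, reached the noise floor on an array, at 125.0 against 200.3 and, in its other probe set, 77.7 against 145.4, which is too few to decide, and Dbp and Tef had 2 probe sets at that level between them, so an error at single probe sets cannot be told apart either; the other Dbp probe set also read lower, at -17.4 against 50.6, but under the noise floor. Of 7 other clock genes above the lower floor, 6 read lower in the high-salt heart, including Nr1d2 at 23.7 against 98.8 and Bhlhe41 at 53.7 against 114.3, but also Bmal1 at 20.6 against 29.5, which different clock times would move against Dbp; all 3 lay under the noise floor. An effect of the diet or the disease on the clock was not tested.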
